A study of Mus musculus with 3 samples.

How the data were processed

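Gene expression was measured in 3 samples of mouse embryonic stem cell-derived astrocytes, all in 1 group. Biotin-labelled material made from total RNA was hybridised to Affymetrix Mouse Genome 430 2.0 arrays (1 colour), per the labels' protocols. The deposited table holds 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes the software was GCOS 1.4. The algorithm settings, the scaling target and any detection calls are not given in the sources used here. The deposited intensities were above 0 in all 45101 rows, from a lowest value of 0.0563 to a highest of 12521. Their means after trimming 2% at each end were 131, 149 and 154 on replicates 1, 2 and 3, so the arrays were not brought to a common trimmed mean over all probe sets. Array images and probe-level values were not used here, so saturation and probe-level background could not be examined.

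Probe sets were named through the platform annotation. Of the probe sets, 34958 had 1 gene, 932 had several and were left out, and 9160 had none there and are unnamed here. The Entrez identifiers were set against the mouse gene table of the GRCm38.p6 assembly to update symbols, which changed 0, and 204 probe sets with identifiers outside that table kept the platform's symbol. No genome build is given for the deposited values, so no coordinates are printed. Log2 was taken of the deposited intensity with no pseudocount. Each of 18194 genes took the value of the probe set with the highest mean over the 3 arrays. Of 6773 genes above background with at least 2 probe sets, 3900 had 1 or more that was not above it, so the probe set rule matters and its alternative is given. Genes with near-identical copies, such as ribosomal protein genes, can share probes with them.

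With no contrast in the design and no detection calls, background was set from 78 genes for olfactory, vomeronasal, trace-amine and taste receptors. The limit of each array was the 95th percentile of their log2 signal, and their median was 1.78. Each of the remaining 18116 genes was tested with limma 3.58.1 in R 4.3.3 on its log2 signal minus the limit of each array (one-sample, one-sided, eBayes, Benjamini-Hochberg adjusted p below 0.05). A gene that did not pass is described as not above background, not as absent. At an unadjusted p below 0.05 the count was 10713. The bootstrap interval of the limit came from 1000 resamples of the receptor genes. The other bootstrap intervals came from 1000 resamples of the genes they describe, which are not replicates. The procedure was tested on simulated data (18116 genes), in which each gene took the root-mean-square SD of real genes of like level. Of 200 genes placed at 1 log2 unit above the limit 19.5% were called, and of 200 at 2 units and 200 at 4 units 100%. Of 200 at the level of the receptor genes 0 were called, but their levels were drawn from the genes that set the limit, so few could be. With 1 simulated value per gene and array, this 0 does not measure false calls that come from taking the brightest probe set. In the measured data 534 genes less than 1 log2 unit above the limit were called, so the 19.5% need not hold for real genes. A gene within about 1 log2 unit of the limit can still go unseen, and 861 genes with a mean above the limit were not called.

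Before the data were examined, 28 gene lists (464 genes, 433 of them measured), the tests and the alternatives were fixed. The lists are astrocyte, reactive astrocyte, neural precursor and radial glia, pluripotency, neuron, oligodendrocyte lineage, microglia and blood, endothelial, mesenchymal, ependymal, endoderm, mesoderm and muscle, epithelial, proliferation, cell cycle brakes and p53 pathway, immediate early and serum response, BMP and JAK-STAT signalling, cholesterol synthesis, interferon response, extracellular matrix and synaptogenic factors, forebrain and midbrain patterning, Hox, germline, imprinted, DNA methylation and Polycomb, housekeeping, sex chromosome and other-tissue genes. A list's count above background was set against 10000 random lists of its size matched on the number of probe sets per gene (two-sided permutation p, adjusted over the 28 lists, with 0.0002 as the smallest unadjusted p it can give). Genes are not replicates, so this p describes these arrays. Adjusted over the list alone, the counts were the same as over all genes tested except for 5 in place of 6 neuronal and 0 in place of 1 mesoderm genes. For shifts between arrays, each gene's deviation from its own mean was taken, less the array's median deviation over all genes above background. The SD over arrays of a list's mean deviation was set against 10000 random lists matched on signal decile (one-sided permutation p). In simulated data 46 of 50 lists of 15 genes moved by 0.5 log2 units on 1 array were called, and 1 of 50 unmoved lists.

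Named genes were set by list order and not by value: the first 8 measured genes of the astrocyte list, 5 of the reactive astrocyte, precursor and pluripotency lists, 3 of the other lists except the other-tissue list, and every sex chromosome gene. To these were added a list's exceptions, where up to 3 members stood on the other side from the rest, and the 10 genes above background with the largest range over the arrays. Alternatives were another percentile, other background genes, the median of a gene's probe sets, leaving out probe sets ending in _s_at, _x_at or _a_at (in the report, those that can bind several transcripts, of the same gene or of others), quantile normalization, log2(signal + 32), leaving out dim genes, a call with no test, eBayes with trend and robust settings, and each array left out in turn. All 3 arrays were kept in the main analysis. Gene families defined by symbol were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.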

Results

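Mouse embryonic stem cells were taken through embryoid bodies (4 days), a selection medium for neural precursors (5 to 7 days) and expansion with FGF2 and an EGF. Precursors 18 passages from the embryoid bodies were then turned into astrocytes by removing the growth factors and adding 5% fetal bovine serum for 5 days. Material made from the total RNA of 3 such samples, labelled wild type, was hybridised to 1-colour Affymetrix Mouse Genome 430 2.0 arrays. All 3 arrays form 1 group, so the design holds no contrast. The comparisons it allows are each gene's signal against background, each gene group against random groups, and the 3 arrays against each other. The median probe-set signal was 20.02, 23.3 and 19.4 on replicates 1, 2 and 3, and no probe set was at or below 0. Nothing in the labels says that the samples came from separate cultures. The p-values therefore measure only the spread between these 3 samples, which may be technical, and their number limits the precision. All levels below are mean log2 signal ± SD (n = 3). The background limit was 3.99, 4.10 and 4.07 log2 units on the 3 arrays, with a mean of 4.05, and a level says nothing about another gene's level, because probe sets differ in brightness.

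Of 18116 genes tested, 10570 (58.3%) were above background and 7546 were not (limma one-sample test, one-sided, Benjamini-Hochberg adjusted p below 0.05). Among housekeeping genes 11 of 12 were above background, among them Actb at 13.30 ± 0.04 and Gapdh at 12.61 ± 0.40, while Gusb, a lysosomal glucuronidase, was at 3.91 ± 0.55 and did not pass, and Hprt lay at 7.16 ± 0.10. None of 19 genes restricted to other tissues, such as insulin and milk protein genes, was above background by limma. Of these, 2 had means above the limit, and 1 had an unadjusted p below 0.05 and lay above the limit on each array, the surfactant protein gene Sftpc at 4.37 ± 0.15, named after its value was seen. Random lists of their size held a median of 10 (two-sided permutation p adjusted over the 28 lists = 0.0022). The 95% bootstrap interval of the limit ran from 3.81 to 4.11 log2 units, and its ends gave 10868 and 10492 genes above background.

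Genes of astrocytes were broadly present. Of 28 measured genes on the astrocyte list, 23 were above background. Gfap, the astrocyte intermediate filament, was at 12.63 ± 0.12. Aqp4, the water channel of astrocyte endfeet, was at 11.87 ± 0.10, and the calcium-binding protein gene S100b was at 9.57 ± 0.19. The glutamate transporters Slc1a3 and Slc1a2 were at 10.95 ± 0.25 and 9.56 ± 0.18. Glul, which makes glutamine from glutamate, was at 10.91 ± 0.39, and Gja1, which encodes a gap junction protein, was at 11.53 ± 0.15. Aldh1l1, a folate enzyme often used as an astrocyte marker, was at 5.45 ± 0.34, above background on 1 of its 2 probe sets (adjusted p = 0.00206, limma). Aldh1l1 was at -0.0740 log2 units from the limit with the median of a gene's probe sets. Without probe sets that can bind several transcripts it was at -1.60. Slc1a2 was above background on 2 of its 5 probe sets. The 5 members not above background were Gjb6, Dio2, Slc6a11, Grm3 and Grm5, a group of 5 named after its values were seen. Their levels were 2.02 ± 1.69, 4.39 ± 0.23, 3.54 ± 0.87, 4.06 ± 1.26 and 4.22 ± 0.57. Random lists held a median of 19 genes above background, and the count of 23 was not distinguishable from them (adjusted permutation p = 0.15). Without replicate 1 the count was 24 and the adjusted p was 0.0432.

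**Figure D1:**
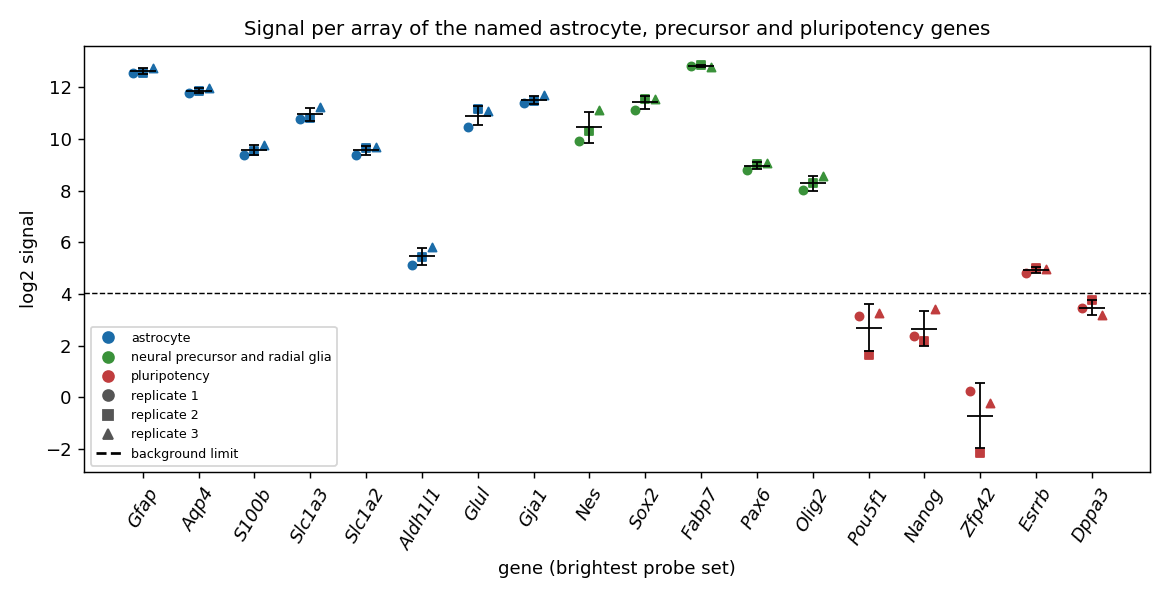
Log2 signal (vertical axis) of the named astrocyte, neural precursor and pluripotency genes (horizontal axis, brightest probe set of each gene); points are the 3 arrays, black bars the mean ± SD, and the dashed line the mean background limit of 4.05. The 8 astrocyte and 5 precursor genes lie above the limit on each array, and of the 5 pluripotency genes Esrrb alone does.

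Every measured gene of the neural precursor and radial glia list, 19 of 19, was above background. Nes, the precursor intermediate filament nestin, was at 10.45 ± 0.60. The transcription factor Sox2 was at 11.42 ± 0.24, and Fabp7, the brain lipid-binding protein of radial glia, was at 12.83 ± 0.02. Pax6 was at 8.97 ± 0.15, on 2 of its 5 probe sets, and Olig2 at 8.29 ± 0.28. The largest adjusted p among the 19 genes was 0.0337 (limma). Random lists held a median of 12 (adjusted permutation p = 0.0022). With the median of a gene's probe sets in place of the brightest, 14 genes were above background and the list no longer stood apart from random lists (adjusted permutation p = 0.18).

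Pluripotency genes were mostly at background level: 2 of 19 were above it, against a median of 10 in random lists (adjusted permutation p = 0.0022). The core factors Pou5f1 and Nanog were at 2.69 ± 0.91 and 2.65 ± 0.67. Zfp42 was at -0.72 ± 1.26 and Dppa3 at 3.47 ± 0.28. The members above background were Esrrb, an orphan nuclear receptor, at 4.93 ± 0.11 (adjusted p = 0.00281, limma), and Klf4, a factor also expressed in differentiated cells, at 5.17 ± 0.23 (adjusted p = 0.00205, limma). Esrrb rested on 1 of 3 probe sets, one of the kind that can bind several transcripts, and was at -1.001 log2 units from the limit when such probe sets were left out, where the list's count was 1. No germline gene was above background (0 of 14, against a median of 6; adjusted permutation p = 0.0028, and 0 at an unadjusted limma p below 0.05). Dazl and Ddx4, both RNA-binding factors of germ cells, were at 2.18 ± 1.60 and 1.39 ± 1.33, and Sycp3, of the meiotic chromosome axis, at 3.87 ± 0.89.

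Neuronal genes split. Of 21 measured, 6 were above background, fewer than the median of 14 in random lists (adjusted permutation p = 0.0031). Map2, a microtubule-associated protein of dendrites, was at 10.91 ± 0.16, Rbfox3, which encodes NeuN, at 6.66 ± 0.30, and Tubb3, a neuronal tubulin, at 5.83 ± 0.65. The synaptic vesicle gene Syt1 was at 7.24 ± 0.12, Dcx, of migrating neurons, at 5.09 ± 0.32, and Scg2, a secretory granule protein, at 4.83 ± 0.56. Syt1 was above background on 1 of its 4 probe sets and Dcx on 2 of 4. Members that were not above background included Snap25 at 2.02 ± 0.50, Stmn2 at 1.93 ± 0.75 and Nefl at 2.10 ± 0.26. The count adjusted over the list alone was 5.

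Genes of the oligodendrocyte lineage also split, with 6 of 16 above background (median of random lists 10, adjusted permutation p = 0.15, and 5 genes with an adjusted permutation p of 0.0467 without replicate 1). Those above background were Olig1 at 11.64 ± 0.09, Pdgfra at 5.80 ± 0.08, Sox10 at 4.64 ± 0.15, Gpr17 at 6.62 ± 0.33 and Nkx2-2 at 5.80 ± 0.39, and the myelin enzyme gene Cnp at 11.72 ± 0.20. Cspg4, which encodes the precursor marker NG2, was at 3.58 ± 0.35 and did not pass on either of its probe sets. Pdgfra and Sox10 were each above background on 1 of 3 probe sets. Mbp, a main protein of myelin, was at 4.55 ± 0.33 and did not pass the test (adjusted p = 0.0678, limma), and none of its 8 probe sets did. Mog and Mag, also of myelin, were at 1.14 ± 1.84 and 2.10 ± 0.23. Of the genes named here, Syt1, Dcx and Scg2 among the neuronal genes and Olig1, Gpr17, Nkx2-2, Cnp, Cspg4, Mog and Mag, together with Snap25, Stmn2 and Nefl, were chosen after their values were seen.

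Markers of microglia and blood, endothelial and epithelial cells were mostly at background level. Of 15 microglia and blood cell genes 1 was above it (median of random lists 8, adjusted permutation p = 0.0022), and this was Csf1r, the receptor for colony-stimulating factor 1, at 5.34 ± 0.18 on 1 of 3 probe sets. Aif1, Itgam and Cx3cr1 were at 1.79 ± 1.62, 1.98 ± 1.19 and 3.08 ± 0.18. The count was 0 with the median of a gene's probe sets and without probe sets that can bind several transcripts. Of 12 endothelial genes 3 were above background (median 6, adjusted permutation p = 0.15), the growth factor receptor Kdr at 6.59 ± 0.46, Egfl7 at 4.99 ± 0.37 and the organic anion transporter Slco1a4 at 9.16 ± 0.39. Pecam1, Cdh5 and Cldn5, of endothelial junctions, were at 1.56 ± 2.00, 2.20 ± 1.16 and 2.92 ± 1.72. Of 12 epithelial genes 1 was above background, Trp63 at 5.03 ± 0.22 (median 7, adjusted permutation p = 0.0031, 0.0982 without probe sets that can bind several transcripts, and 2 genes without replicate 2), and Cdh1, Epcam and Krt8 were at 0.99 ± 1.30, 4.48 ± 0.52 and 3.69 ± 0.14. Trp63 passed on 1 of 4 probe sets. With the median of a gene's probe sets it was at -0.56 log2 units from the limit and the epithelial count was 0.

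Of 16 mesenchymal genes measured, 8 were above background, close to the median of 10 in random lists (adjusted permutation p = 0.61). Smooth muscle actin Acta2 was at 9.83 ± 0.21, and the contractile genes Myl9, Tagln and Cnn1 were at 9.83 ± 0.25, 7.71 ± 0.14 and 5.83 ± 0.04. Acta2 was above background on 1 of its 3 probe sets. It was at -2.003 log2 units from the limit with the median of a gene's probe sets, where 4 genes of the list were above background, and at -2.43 without probe sets that can bind several transcripts. The matrix protein gene Fbln1 was at 6.19 ± 0.32, and the transcription factor genes Twist1 and Prrx1 were at 7.58 ± 0.22 and 6.09 ± 0.37, all above background, though Fbln1 on 1 of 3 probe sets and Prrx1 on 1 of 6. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 were at 2.85 ± 0.50, 3.72 ± 0.75 and 2.59 ± 0.69, and the receptor Pdgfrb was at 1.25 ± 1.66, none of them above background. Among 10 ependymal genes 5 were above background (median 5, adjusted permutation p = 1). Foxj1, the master regulator of motile cilia, was at 9.76 ± 0.49 and Ccdc153 at 6.21 ± 0.07, while Rsph1, of the ciliary radial spoke, ranged from 3.05 to 5.65 over the arrays and did not pass (adjusted p = 0.901, limma). Without probe sets that can bind several transcripts the ependymal count was 2. Fbln1, Twist1, Prrx1, Myl9, Tagln, Cnn1, Col1a2 and Col3a1 were named after their values were seen.

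Of the other germ layers, 4 of 12 endoderm genes and 1 of 12 mesoderm and muscle genes were above background, against medians of 8 and 7 in random lists (adjusted permutation p = 0.0465 and 0.0022). Sox17 and Foxa2 were at 3.65 ± 0.46 and 3.79 ± 0.60 and did not pass, and Gata4 passed at 5.10 ± 0.45, on 1 of 2 probe sets. Foxa1, the endoderm gene farthest above the limit and named after its value was seen, passed at 8.81 ± 0.16. Mesp1, Nkx2-5 and the cardiac myosin gene Myh6 were at 4.45 ± 0.35, 4.44 ± 0.22 and 2.97 ± 0.57, and the member that passed was Tbx6 at 4.68 ± 0.33 (adjusted p = 0.0251, limma). Adjusted over the list alone, 0 mesoderm genes passed (limma), and 2 had an unadjusted p below 0.05. The mesoderm count was 0 without replicate 1 or without replicate 2, and 2 without replicate 3. The endoderm count lost its distinction from random lists under 5 of 12 alternative settings, with adjusted permutation p up to 0.445, and was 2 with the limit at the 99th percentile.

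**Figure D2:**
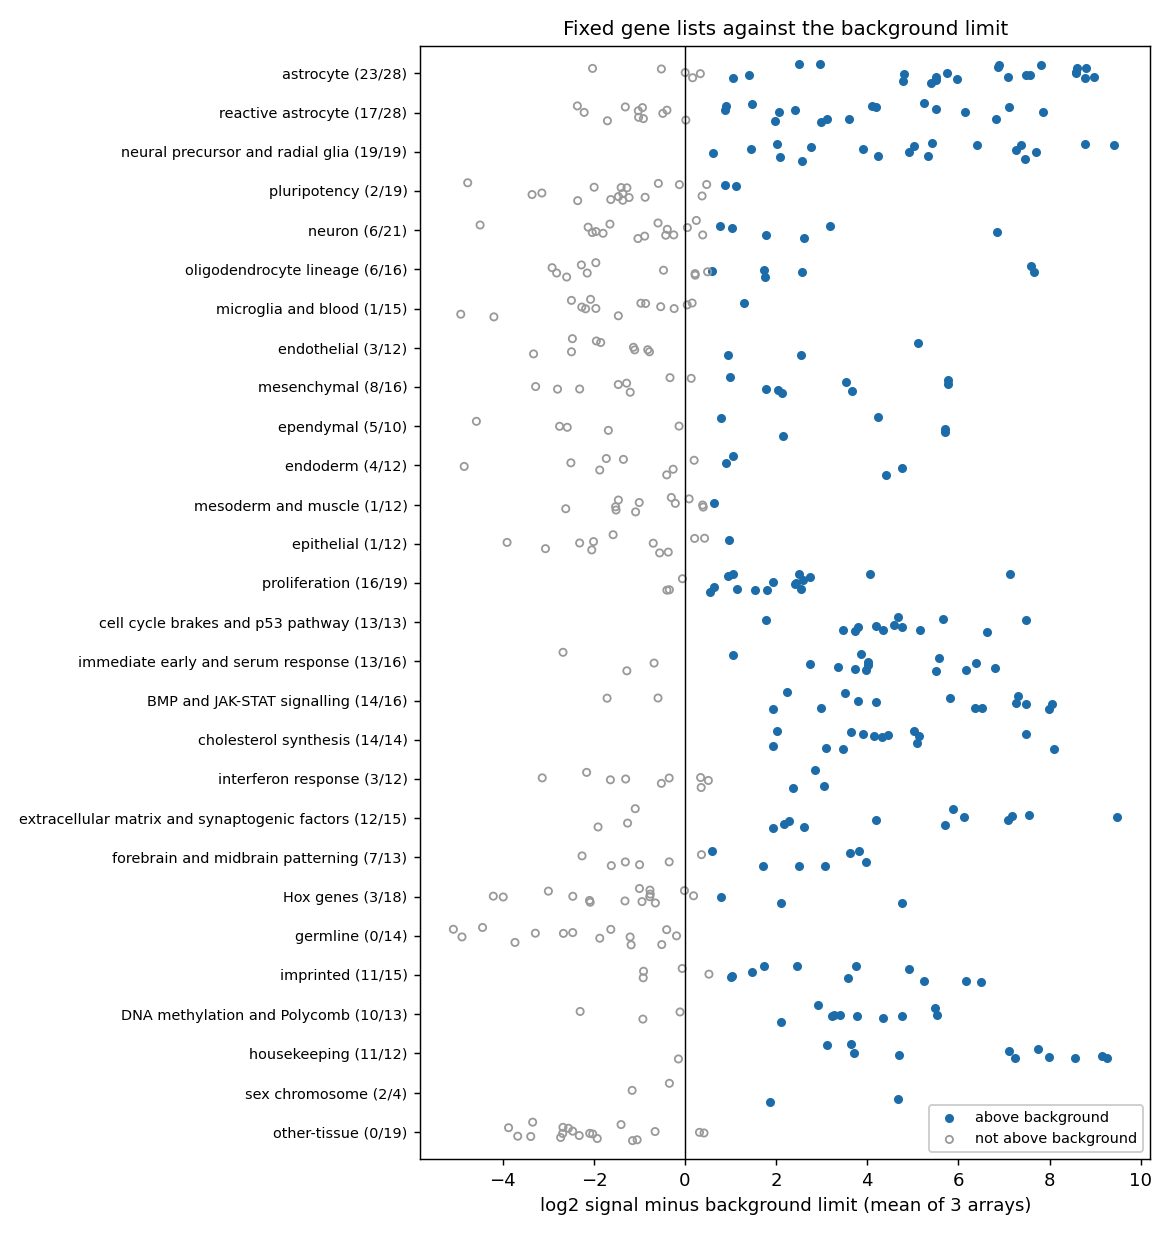
Mean log2 signal over 3 arrays minus the background limit (horizontal axis) of each measured gene of the 28 fixed lists (rows), with the number above background and the number measured in parentheses; filled points passed the limma test and open points did not, and the vertical scatter within a row is only for display. Precursor, cell cycle brake and cholesterol genes are all filled, and germline and other-tissue genes are all open.

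Genes that halt the cell cycle or respond to p53 were above background without exception (13 of 13, median of random lists 8, adjusted permutation p = 0.0031). Cdkn1a, which encodes p21, was at 10.68 ± 0.13. Cdkn2a and Cdkn2b, from the locus of p16, p19ARF and p15, were at 7.51 ± 0.38 and 8.64 ± 0.11. Proliferation genes were also above background in most cases (16 of 19, median 12), and their count was not distinguishable from that of random lists (adjusted permutation p = 0.17). Mki67 was at 5.58 ± 0.51 and Top2a at 6.56 ± 0.34, on 1 of 3 probe sets, and the members that did not pass were Ccnb2 at 3.71 ± 0.42, Bub1 at 4.00 ± 0.05 and Aurkb at 3.65 ± 0.49.

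Genes tied to serum and to gliogenic signals were widely above background. Of 16 immediate early and serum response genes 13 were (median 8, adjusted permutation p = 0.0462), including Fos at 10.43 ± 0.35, Egr1 at 9.62 ± 0.81 and the matrix protein gene Ccn1 at 10.86 ± 0.17. Fosb, Egr2 and Ankrd1 were at 2.78 ± 0.66, 3.37 ± 0.85 and 1.38 ± 0.32 and did not pass. This list lost its distinction under 3 of 12 alternative settings, with adjusted permutation p up to 0.119. Of 16 genes of BMP and JAK-STAT signalling, pathways that promote astrocyte fate, 14 were above background (median 11, adjusted permutation p = 0.22). The BMP target genes Id1 and Id3 were at 11.35 ± 0.19 and 12.10 ± 0.10, and Stat3 was at 10.41 ± 0.22. The ligand genes Bmp4 and Lif were at 2.34 ± 0.64 and 3.46 ± 0.17 and were the members that did not pass.

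All 14 cholesterol synthesis genes were above background (median 9, adjusted permutation p = 0.0076). Hmgcs1 and Sqle, enzymes of sterol synthesis, were at 12.15 ± 0.23 and 11.53 ± 0.16, and the sterol sensor Insig1 was at 7.96 ± 0.17. Genes of the extracellular matrix and of factors that promote synapses were above background in 12 of 15 cases (median 11, adjusted permutation p = 0.81). Sparc was at 13.54 ± 0.06, Fn1, which encodes fibronectin, at 11.23 ± 0.18, and Thbs1, a synapse-promoting thrombospondin, at 8.24 ± 0.18, while Thbs2, Acan and Nid1 were at 2.79 ± 0.17, 2.14 ± 1.07 and 2.96 ± 0.78.

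Genes linked to reactive astrocytes were above background in 17 of 28 cases, close to the median of 18 in random lists (adjusted permutation p = 0.98). Lcn2, which encodes the secreted protein lipocalin 2, was at 7.16 ± 0.15, Serpina3n, a protease inhibitor, at 9.30 ± 0.10, and the hyaluronan receptor Cd44 at 10.20 ± 0.21. Timp1 was at 4.07 ± 0.43 and did not pass. Steap4 was at 0.49 on replicate 1 and at 5.25 and 5.23 on replicates 2 and 3, and passed the test only without replicate 1, by 1.15 log2 units (adjusted p = 0.0101, limma). Interferon response genes were above background in 3 of 12 cases (median 6, adjusted permutation p = 0.25), namely Ifit3 at 7.11 ± 0.14, Irf9 at 6.92 ± 0.33 and Ifi35 at 6.42 ± 0.21, while Ifit1 and Irf7 were at 4.41 ± 0.52 and 3.53 ± 0.73 and did not pass. The interferon count was 1 without probe sets that can bind several transcripts.

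Regional identity genes of the forebrain and midbrain were above background in 7 of 13 cases (median 6, adjusted permutation p = 0.94). Otx2, of the anterior brain, was at 7.12 ± 0.52 and the forebrain factor Emx2 at 6.55 ± 0.48, and En1, of the midbrain and hindbrain border, was at 4.41 ± 0.68 and did not pass (adjusted p = 0.248, limma). En2 and Gbx2, of the same border and named after their values were seen, were at 8.02 ± 0.32 and 4.63 ± 0.15 and passed. Of 18 Hox genes, which specify the hindbrain and spinal cord, 3 were above background (median 10, adjusted permutation p = 0.0045). These were Hoxa5 at 8.81 ± 0.14, Hoxa3 at 6.16 ± 0.41, on 2 of 4 probe sets, and Hoxd8 at 4.85 ± 0.25, on 1 of 2. Hoxa2 and Hoxb2 were at 4.04 ± 0.69 and 3.28 ± 1.84 and did not pass, and the count was 1 with the median of a gene's probe sets.

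Of 13 genes of DNA methylation and Polycomb repression, 10 were above background (median 9, adjusted permutation p = 1). The maintenance methyltransferase Dnmt1 was at 7.32 ± 0.32 and the de novo enzyme Dnmt3a at 8.82 ± 0.19. Dnmt3b, the second de novo enzyme, Uhrf1, the partner of Dnmt1, and Tet3 were at 3.94 ± 0.53, 3.13 ± 1.82 and 1.75 ± 1.66 and did not pass. Imprinted genes, expressed from 1 parental allele, were above background in 11 of 15 cases (median 10, adjusted permutation p = 0.99). Peg3 was at 10.23 ± 0.22, Igf2 at 5.06 ± 0.67 and Meg3 at 5.52 ± 0.31, and Meg3 rested on 1 of 11 probe sets and Igf2 on 1 of 2. With the median of a gene's probe sets Igf2 was at -0.64 log2 units from the limit and Meg3 at -1.23. The imprinted count was 5 with the median of a gene's probe sets and 6 without probe sets that can bind several transcripts. Of 4 sex chromosome genes 2 were above background (median 3, adjusted permutation p = 0.529, and 1 gene with the median of a gene's probe sets). The Y-linked Eif2s3y and Uty were at 8.73 ± 0.56 and 5.92 ± 0.26 and passed, on 1 of 2 and 2 of 4 probe sets. The Y-linked Kdm5d was at 2.89 ± 1.11 and did not pass. Xist, the RNA that silences an X chromosome in female cells, was at 3.71 ± 0.49 and did not pass on any of 3 probe sets.

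Over the 10570 genes above background, across genes that are not independent replicates and differ widely in level, replicates 1 and 2 had a Pearson r of 0.990 and a Spearman rho of 0.990. The values were 0.974 and 0.973 for replicates 1 and 3, and 0.979 and 0.978 for replicates 2 and 3. The mean Pearson r of the pairs was 0.981, and 0.943 over all genes tested. The median SD over the arrays was 0.24 log2 units, and 639 genes had a range above 1 log2 unit. Over all 18116 genes tested, the median SD was 0.35 and 5977 genes had such a range, and the test itself favours genes with a small SD. No pair of arrays held an identical value for any probe set. The median difference in log2 signal was -0.35 for replicate 1 minus replicate 3 and -0.18 for replicate 1 minus replicate 2. Of the 100 genes with the largest range, replicate 3 was the array farthest from the middle value in 68, replicate 1 in 28 and replicate 2 in 4. Over all 10570 genes these numbers were 5062, 3963 and 1545. The ranges and these numbers come from arrays not brought to one median. The median differences above by themselves favour replicate 2 as the middle array.

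The 10 genes above background with the largest range were Sox11, Sbno2, Ncan, Khsrp, Prune2, Ctse, Zbtb7b, Slc8a1, Nbeal1 and Rab5b. This ranking used arrays not brought to one median, so it can depend on the differences in level between them. Sox11, a transcription factor of immature neural cells, was at 8.68 and 8.63 on replicates 1 and 2 and at 5.82 on replicate 3. Ncan, which encodes the brain matrix proteoglycan neurocan, was at 11.02, 10.84 and 8.69 in the same order, and Prune2 at 10.73, 10.92 and 8.75. Ctse was at 6.51, 6.33 and 4.41, Slc8a1 at 5.98, 6.37 and 4.32, Nbeal1 at 8.43, 9.20 and 7.17, and Rab5b at 6.57, 6.28 and 4.55. Sbno2 was at 5.04, 5.78 and 7.79, Khsrp at 5.56, 6.36 and 7.80, and Zbtb7b at 5.03, 6.52 and 7.10. These are single arrays and single probe sets, so the differences have no replicate check. With the arrays brought to one median, the probe set of Sox11 was at -3.12 log2 units on replicate 3 from the mean of the others, and the median of its 5 other probe sets was at -0.07. The values were -2.53 and 0.66 for Ncan with 2 other probe sets, 1.56 and 0.000419 for Khsrp with 2, and -1.93 and -1.63 for Nbeal1 with 3.

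No gene list shifted between the arrays by more than random lists of like signal after adjustment (17 lists with at least 5 members above background, one-sided permutation test). At an unadjusted permutation p below 0.05 there were 2. The deviations here are relative to each array's median deviation over the genes above background, so they are not raw moves. Imprinted genes had a mean deviation of 0.10, 0.15 and -0.25 log2 units on replicates 1, 2 and 3 (11 genes, adjusted permutation p = 0.07). Without Igf2, whose removal lowered the SD between arrays the most, these were 0.09, 0.10 and -0.19 (unadjusted permutation p = 0.0291). Matrix genes had 0.08, 0.09 and -0.17 (12 genes, adjusted permutation p = 0.19), and without Ncan -0.0015, 0.0348 and -0.0337 (unadjusted permutation p = 0.77), so that 1 probe set carried most of this deviation, while without Thbs1 the unadjusted permutation p was 0.0519. Leaving out members was chosen after the values were seen. The mean deviation of the astrocyte list, on this relative scale, was less than 0.01 log2 units in size on each array (23 genes, adjusted permutation p = 0.98). Single members moved more and in either direction. Kcnj10 was at 5.85 on replicate 1 and 7.12 on replicate 3, and Ntsr2 at 5.31 and 4.83, both named after their values were seen. With the median of a gene's probe sets, 1 of 13 lists passed, the cell cycle brakes and p53 pathway, with an SD of 0.31 log2 units between arrays (adjusted permutation p = 0.0052).

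Control transcripts with separate probe sets at their 3′ and 5′ ends set replicate 3 apart. The 3′ minus 5′ log2 difference of Actb was 0.16, 0.23 and 0.98 on replicates 1, 2 and 3, and that of Gapdh was -0.38, -0.38 and 0.31. For the Bacillus transcript dap it was 0.84, 1.08 and 2.75, and for thr 0.76, 0.59 and 2.69. The hybridisation controls bioB, bioC, bioD and cre, which are supplied already labelled, differed on replicate 3 from the mean of the others by -0.02 to 0.10. The means above include replicate 3. Gapdh's gene value came from its 5′ probe set, which was at 12.88, 12.80 and 12.15 on replicates 1, 2 and 3. Counts without replicate 3 were 10451 genes above background in all, 23 of 28 astrocyte genes, 18 of 19 precursor genes and 2 of 19 pluripotency genes.

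**Figure D3:**
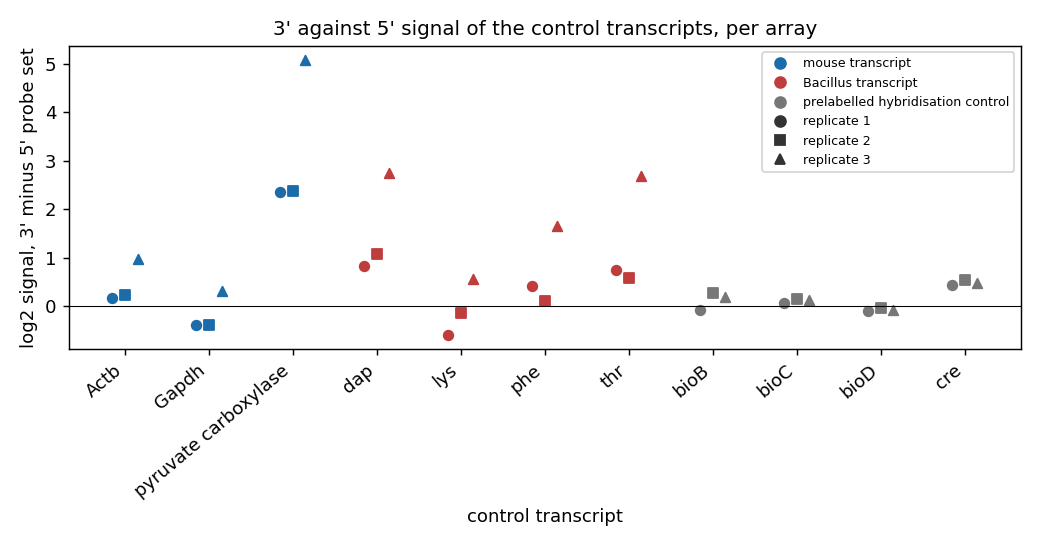
Log2 signal of the 3′ probe set minus that of the 5′ probe set (vertical axis) for control transcripts (horizontal axis); colours mark mouse transcripts, Bacillus transcripts and prelabelled hybridisation controls, and symbols mark the 3 arrays. Replicate 3 lies above both other arrays for the 3 mouse and 4 Bacillus transcripts, and within 0.104 of their mean for the 4 prelabelled controls.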

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

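The tests of technical explanations below were chosen, or changed to their present form, after the values they rest on had been seen.

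Among probe sets with no gene in the annotation, which the report does not use, 975 of 9160 (10.6%) were above the background limit by the same limma test. The 3′ control probe set for 18S ribosomal RNA, outside the gene-level measurement, had a signal of 500.2 on replicate 3 against 105 and 130 on replicates 1 and 2. This lay above the background limit of 16.8 on that array. The middle probe set of 18S had signals of 58.4, 93.1 and 149 on replicates 1, 2 and 3, and the 5′ probe set 48.6, 76.3 and 124.

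Replicate 3 had more 3′ than 5′ signal in its control transcripts. Bacillus transcripts, which do not come from the cells, shifted too, by at least 0.92 log2 units. Their largest difference between replicates 1 and 2 was 0.45. Their signals were not set against the limit, and whether and when they were added was not examined. The unspiked trp control, below the limit on each array, moved on replicate 3 by 1.99 log2 units at its 3′ and 0.26 at its 5′ probe set. Its middle probe set moved the other way, by -0.76. The Bacillus shifts therefore cannot decide whether RNA broken in the cells or during extraction was the whole cause. Hybridisation, washing and scanning are argued against by the prelabelled controls, whose highest shift was 0.10. Shorter copies made during cDNA synthesis and labelling are a candidate explanation. Each mouse transcript shifted by at least 0.69 against 0.06 between replicates 1 and 2. This shift is the pattern itself, so it cannot tell short copies from broken RNA. The design gives no biological explanation to test, and breakage of the cells' own RNA stays open.

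With arrays not brought to one median, replicate 3 stood apart in 68 of the 100 genes with the largest range. It did so in 5062 of all 10570 genes above background. The moves that follow are with the arrays brought to one median. For Sox11 and Ncan the other probe sets did not follow the gene's own move, with -0.07 against -3.12 log2 units and 0.66 against -2.53, while the 3 others of Nbeal1 moved by 0.843 times its own move. Another probe set above the limit existed for 37 of the 100 genes. On the values brought to one median, replicate 3 stood apart in 27 of them. In these 27 the median ratio of the others' move to the gene's own was 0.161 (95% bootstrap interval 0.000269 to 0.338), and 6 moved by at least 0.5 times as far. Picking genes by the range of their own probe set lowers this ratio by itself, so a change of the whole gene stays open for the group. The 3′ bias of replicate 3 stays open too, because the share of the 27 genes in which the gene's own probe set gained on its others, 59.3%, goes in all but 1 of them with the sign of the move by which they were picked and decides nothing. The brightest and dimmest probe sets were also compared over 4955 genes with at least 2 above the limit, not picked by range. Ranked on replicate 2, the brightest gained on replicate 3 against replicate 1 by a median of 0.24 log2 units (95% bootstrap interval 0.22 to 0.27, above 0 in 62.9%). Ranked on replicate 3, it gained 0.04 on replicate 2 against replicate 1. The arrays were brought only to one median, so an array difference that depends on brightness could give this gain without 3′ bias. The gain bears on levels read from the brightest probe set, and probe positions were not used here.

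Acta2 and Myl9 were above background while Col1a1, Col1a2 and Col3a1 were not, although other collagen genes such as Col11a1 and Col5a1 were. This was picked after the values were seen, and the mesenchymal list as a whole was at 8 of 16 (adjusted permutation p = 0.61). Fibroblasts or feeder cells as an abundant part of the cultures are argued against by Dcn, Lum and Postn, fibroblast transcripts outside this observation, of which 0 were above background and whose median was -2.31 log2 units from the limit (median SD 1.55). Other mesenchymal genes of the same list went the other way, with Twist1 at 7.58 ± 0.22, Prrx1 at 6.09 ± 0.37 and Fbln1 at 6.19 ± 0.32 above background, the last 2 on 1 of 6 and 1 of 3 probe sets, so a small share of mesenchymal cells stays open. Expression of contractile genes by the astrocytes in serum stays open as a hypothesis and was not tested, and Acta2 rests on 1 probe set of a kind that can bind related actin transcripts.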

How the results depend on the processing

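The count of genes above background ranged from 9070 without probe sets ending in _s_at, _x_at or _a_at to 10839 for the call with no test, and stayed within 1.5 times of 10570 under all 12 alternatives. Of 336 list counts under these alternatives, 312 were within 1.5 times of the main count. The counts that moved were these. Pluripotency fell from 2 to 1 under the 99th percentile, the median of probe sets and without _s_at, _x_at and _a_at probe sets. Endoderm fell to 2 and mesoderm to 0 under the 99th percentile, mesoderm to 0 with the other-tissue limit, and mesoderm rose to 2 with dim genes left out or with no test, where the other-tissue count rose from 0 to 1. With the median of probe sets, microglia and blood fell to 0, mesenchymal to 4, epithelial to 0, Hox to 1, imprinted to 5 and sex chromosome to 1. Without _s_at, _x_at and _a_at probe sets, microglia and blood fell to 0, ependymal to 2, interferon to 1 and imprinted to 6. Leaving out 1 array in turn gave 0 to 2 mesoderm genes and 1 to 2 epithelial genes. Against random lists, pluripotency, neuron, microglia, mesoderm, cell cycle brake, cholesterol, Hox and germline lists kept their call under all 12 alternatives, with the highest adjusted permutation p at 0.0448. The other-tissue list did so under those that do not take the limit from its own genes. Over all genes tested, the mean Pearson r between arrays was 0.943 in place of 0.981 and the mean over pairs of the median absolute difference, after the pair's median difference was taken off, 0.338 in place of 0.214 log2 units. The number of lists shifting between arrays was 1 with the median of probe sets and 0 otherwise. No paired analysis was possible because there is 1 group.

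Of 1496 values of named genes under the alternatives, 1414 kept their side of the limit and of the test, and 35 changed side of the limit. Among values that stayed on their side of the limit, 41 lost the call and 6 gained it. Calls lost or gained among the 35 are not in these 2 numbers. The 35 values that changed side, as log2 units from the limit, were these. With the 99th percentile, Timp1 was at -0.36, Ifit1 at -0.0193 and En1 at -0.0127, and with the other-tissue limit Timp1 was at -0.20. With the median of probe sets, Aldh1l1 was at -0.0740, Esrrb at -0.94, Mbp at -1.82, Acta2 at -2.003, Epcam at -0.42, Top2a at -0.15, Hoxa2 at 0.0128, Igf2 at -0.64, Meg3 at -1.23 and Trp63 at -0.56. Without _s_at, _x_at and _a_at probe sets, Aldh1l1 was at -1.60, Esrrb at -1.001, Acta2 at -2.43, Top2a at -0.18, Meg3 at -0.0672 and Ifi35 at -0.47. With log2(signal + 32), Steap4 was at 0.17, Rsph1 at 0.0738 and Hoxa2 at 0.0201. Leaving out 1 array in turn gave -1.17 to 1.15 for Steap4, -0.98 to 0.33 for Rsph1, -1.71 to 0.0346 for Uhrf1, -0.42 to 0.0853 for Gusb, -0.19 to 0.21 for Timp1, -0.35 to 0.35 for Hoxa2, -0.58 to 0.33 for Sycp3, -0.45 to 0.0918 for Dnmt3b, -0.51 to 0.0741 for Foxa2 and -1.41 to 0.30 for Hoxb2. The probe set alternatives changed both the probe sets used and the limit, and the 2 were not told apart. Hoxa2 is an exception, since its single probe set stayed and only the limit moved. For the other alternatives the cause was not tested. Signal over background limits what can be said of genes near the limit.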

Other observations

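The gene families below were defined by symbol after the data had been seen, and 24 were compared with random lists of the same size in the same way as the fixed lists.

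Families of basic cell machinery were above background almost throughout. Of 35 complex I subunits 34 were, of 43 cytosolic ribosomal proteins 39, and of 39 proteasome subunits 35 (medians of random lists 22, 26 and 23, adjusted permutation p = 6e-04 for each, whose unadjusted p of 0.0002 is the smallest that the random lists can give). Ribosomal protein genes have near-identical pseudogenes, which probes can share, so their count is uncertain. For all families the count is of genes passing the limma test. The proteasome genes not above background were Psmb8, Psmb9, Psma8 and Psmb11. Of 10 frizzled receptors, which bind Wnt ligands, 9 were above background (median 7, adjusted permutation p = 0.376), and of 19 Wnt ligands 7 were (median 11, adjusted permutation p = 0.175).

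Several ion channel and immune families were above background in fewer cases than random lists. Of 80 potassium channel genes 20 were (median 48, adjusted permutation p = 6e-04), among them Kcnj10 at 6.56 ± 0.65 and Kcnj16 at 7.50 ± 0.17, inward rectifiers found in astrocytes, and Kcnd3 at 10.06 ± 0.34. Of 15 GABA-A receptor genes 3 were (median 10, adjusted permutation p = 0.0021), with Gabrg1 at 8.02 ± 0.40. Of 14 connexin genes 2 were, Gja1 and Gjc1 (median 8, adjusted permutation p = 0.0057). Of 28 interleukin genes 3 were, Il18 at 8.51 ± 0.05, Il17d at 6.85 ± 0.20 and Il33 at 5.83 ± 0.35 (median 13, adjusted permutation p = 6e-04). Of 32 chemokine genes 8 were (median 17, adjusted permutation p = 0.0024), with Cx3cl1 at 9.09 ± 0.33 and Ccl2 at 6.71 ± 0.22. Of 42 collagen genes 13 were (median 26, adjusted permutation p = 6e-04), with Col4a5 at 10.72 ± 0.32 and Col11a1 at 9.19 ± 0.31. Of 22 genes with an Fgf symbol 4 were (median 13, adjusted permutation p = 6e-04). These were Fgf1 at 7.80 ± 0.24, Fgf11 at 5.59 ± 0.25, Fgf12 at 5.27 ± 0.22 and Fgf13 at 4.90 ± 0.47. All levels are mean log2 signal ± SD (n = 3), and genes named here were chosen after their values were seen.

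Of the other families, keratins had 4 of 44, sodium channel alpha subunits 2 of 8 and LIM homeobox factors 2 of 10 above background, each fewer than in random lists (adjusted permutation p = 6e-04, 0.0192 and 0.0347). Glutamate receptors, calcium channel subunits, Sox and forkhead factors, integrins, cathepsins, semaphorins, ephrins with Eph receptors, and protocadherins were not distinguishable from random lists, with adjusted permutation p from 0.0723 to 0.899.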
